A study of Mus musculus with 62 samples.

How the data were processed

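RNA of mouse gastrocnemius muscle was sequenced in 62 libraries from female mice that were injected at 2 months of age. The mice received melanoma cells that cause cachexia (CAC), melanoma cells that do not (NCAC) or a mock injection (Con), and muscle was taken 2, 4, 6 or 8 weeks later. The labels give poly(A)-selected stranded libraries sequenced on an Illumina NovaSeq instrument and the mouse genome build mm10. The aligner, the counting program and the annotation are not given in the sources used here.

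The deposited table holds values in TPM for 47643 gene symbols, 1 column per library, and the values of each library sum to the same total. The group of each library was taken from its description, which matched its title; 1 tag in the labels names cachectic melanoma cells for every library and was not used. The sources also differ on the strain of the mice. The series design describes nude mice and the sample labels name another strain, and which was used is not known here. No comparison uses the strain, but the reading of the lists of immune cells and of melanocyte and tumour markers may depend on it. The replicate numbers do not pair the mice of different groups.

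The reads behind each value were recovered from the TPM, the exon length of each gene in the GENCODE annotation of build mm10, and the smallest step between values of a library. Lengths were matched for 45090 of the 47643 symbols, which held at least 96.98% of the TPM of each library. Of the recovered values of 1 to 20 reads, 77.9% to 79.5% per library lay within 0.02 of a whole number. The estimated depth was 39.62 to 48.34 M reads (M for mega), with a median of 46.24 M. It was 39.62 to 48.34 M in CAC, 43.98 to 47.68 M in NCAC and 43.42 to 47.51 M in Con. A value of 1 TPM for a transcript of 1000 bases stood for 16.4 to 21.2 reads. These figures are estimates, and they describe counting error only.

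Genes with a TPM of at least 1 in at least 5 libraries were tested, which left 12364 genes, 856 of them predicted gene models. The values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, in 1 linear model with a mean for each of the 12 groups and a variance trend on mean expression. The tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the 12364 genes of a comparison, with a threshold of 0.05. At each week, CAC was compared with Con, CAC with NCAC and NCAC with Con, which made 12 comparisons. An F test asked for each of CAC and NCAC whether the difference from Con changed between the 4 weeks. The SE of a log2 change is the moderated one of limma, and its fold is taken on TPM + 1. Means and SD of TPM are plain values over libraries.

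Before the data were examined, 34 gene lists were written down for pathways, complexes and cell types, together with 18 sentinel genes, the comparisons, the threshold, the rule for naming genes and most of the alternatives. Each list was tested against all other genes with camera of limma, which uses a preset correlation of 0.01 between genes, and p was adjusted over the 34 lists of a comparison. Each camera test was repeated with an estimated correlation. For each list, the calls over all genes and those adjusted over the list alone were counted. Of the 34 lists, 15 share at least 1 gene with another list.

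Genes were named by a fixed rule. It took the 18 sentinel genes, the 8 largest rises and the 8 largest falls of a comparison, and up to 3 members of lowest p from each list that camera called. A rise or fall was eligible when it was called and when all libraries of 1 group lay on the same side of the mean of the other group, and genes with clone names were passed over. For the tests across weeks, the 18 sentinel genes and the 8 genes of lowest p were taken. Genes outside this rule are marked where they are named as chosen after their values were seen.

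The method was tested on simulated data made from the real libraries, with 200 genes changed in each of 3 comparisons. In CAC and Con at 8 weeks, 75.0% of genes changed 1.5-fold, 98.4% of those changed 2-fold and 100% of those changed 4-fold were called. In NCAC and Con at 8 weeks these shares were 81.8%, 94.0% and 98.5%, and in CAC and Con at 2 weeks they were 69.1%, 94.0% and 98.5%. Among unchanged genes 6, 8 and 9 were called in these 3 comparisons. Camera called the list that had been moved in each comparison and 0 of the other 33. The simulated noise was independent between genes, with the same SD of a gene in all groups. These results therefore do not cover correlated genes or a spread that differs between groups.

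The alternatives were a pseudocount of 0.1, no filter, a stricter filter at 5 TPM, median-ratio scaling, genes encoded in mitochondrial DNA left out, array weights, a fit of the 2 groups compared only, a block for the replicate number, and each library left out in turn. Median-ratio scaling, called rescaling below, sets the median ratio of genes to a common reference to the same value in every library. Another 4 alternatives were added after seeing the data. They were voom on the recovered reads, a fit of the Con and NCAC libraries only, a correction of each library for a trend on exon length, and a fit without CAC 8 weeks replicate 3 and NCAC 8 weeks replicate 3, which stood apart from their groups. For marker lists of cell types at 8 weeks, exact permutation p values came from all 792 divisions of the CAC and Con libraries. The joint test of 5 lists centred each library on its mean over the lists and summed the squared changes. For a mixture, each CAC share allows a range of TPM per gene, taken from the other CAC libraries and the Con and NCAC libraries at 8 weeks, and the share that left the fewest genes outside was used. Raw reads, splice forms and muscle mass were not analysed here.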

Results

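Cachexia is a loss of muscle and fat that accompanies some tumours. The gastrocnemius, a calf muscle made mostly of fast fibres, was profiled in mice carrying cachectic melanoma cells (CAC), in mice carrying non-cachectic melanoma cells (NCAC) and in mock-injected mice (Con). There were 5 libraries in each group at 2, 4, 6 and 8 weeks, except for 7 in CAC at 8 weeks. The estimated depth was 39.62 to 48.34 M reads per library. Between 16686 and 18167 genes were above 0 TPM in a library, and 24293 of the 47643 symbols were at 0 in all 62. The first principal component held 49.1% of the variance and the second held 7.55%. Values are mean TPM ± SD over libraries, and changes are log2 ratios on TPM + 1 with the adjusted p of limma.

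The composition of the RNA changed along with the genes described below. Genes encoded in mitochondrial DNA held 34.1% ± 0.821 of the TPM in Con, 32.6% ± 2.12 in CAC and 36.4% ± 1.33 in NCAC at 2 weeks (SD, n = 5). In CAC the share was 28.6% ± 2.85 at 4 weeks, 24.9% ± 4.00 at 6 weeks (SD, n = 5) and 24.2% ± 3.53 at 8 weeks (SD, n = 7). In Con it was 33.1% ± 2.85, 33% ± 2.47 and 33.5% ± 3.03 at these weeks, and in NCAC 33.2%, 36.7% and 32.2%. The 20 most abundant genes held 41.2% of the TPM in CAC at 8 weeks and 51.5% in Con. Because TPM is a share, rescaling lowered the median CAC against Con ratio over genes by 0.0837, 0.159, 0.268 and 0.339 on the log2 scale at 2, 4, 6 and 8 weeks. It lowered the median CAC against NCAC ratio by 0.123, 0.164, 0.362 and 0.362. Single genes could shift by more or less. Rescaled counts are therefore given for the lists whose counted calls it changed, and for part of the named genes that lost their call.

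**Figure D1:**
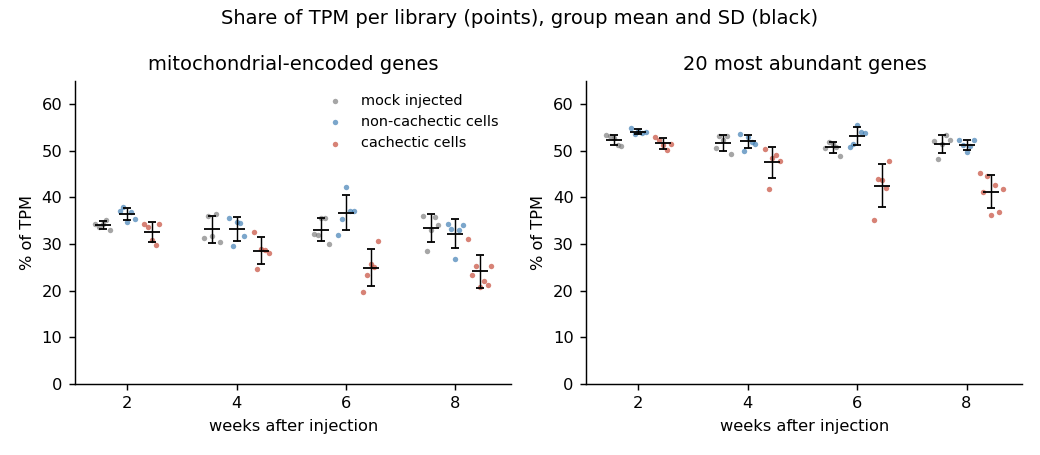
Share of TPM (%) in each library (points), with the group mean and SD (black), for genes encoded in mitochondrial DNA (left) and for the 20 most abundant genes (right), against weeks after injection. In mice with cachectic cells the mitochondrial share was 32.6% at 2 weeks and 24.2% at 8 weeks, and in mock-injected mice it was 34.1% and 33.5%.

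The comparison of CAC with Con at 2 weeks asked what changed in muscle early after the injection of cachectic cells. Stat3, the transcription factor activated by interleukin-6 type cytokines, was at 30.6 ± 8.22 TPM in CAC and 11.8 ± 1.12 TPM in Con (SD, n = 5), a log2 rise of 1.27 (SE 0.129, adjusted p = 1.66e-09). It lies on chromosome 11 from 100885098 to 100939540. Socs3, the feedback inhibitor of STAT3 signalling, rose from 3.00 ± 1.22 to 28.8 ± 27.1 TPM, a log2 change of 2.29 (SE 0.417, adjusted p = 0.00207). Complement C4b rose by 2.00 (adjusted p = 0.0123), and Aldh1a2, which makes retinoic acid, by 1.98 (adjusted p = 0.0113). The ion channel genes Tmem176b and Tmem176a rose by 1.46 and 1.29, and the phospholipid flippase gene Atp9a by 1.41. Cox7a2, a subunit of cytochrome c oxidase, fell by 0.37 (adjusted p = 0.031).

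Of the 22 tested genes of the STAT3 and acute phase list at 2 weeks, 3 rose and 19 were not called, with 12 rises when p was adjusted over the list alone and 4 after rescaling. The list stood above other genes (camera adjusted p = 7.37e-09; adjusted p = 0.426 with an estimated correlation). Of 81 nuclear genes of oxidative phosphorylation, 2 fell and 79 were not called, and 60 fell when adjusted over the list alone. This list stood below other genes (camera adjusted p = 7.64e-68; adjusted p = 0.0202 with an estimated correlation). The 2 were Cox7a2 and Ndufs4, a complex I subunit that fell by 0.30 (adjusted p = 0.0485; 0.0512 after rescaling). Of 13 macrophage markers 0 were called, and 12 rose when adjusted over the list alone (camera adjusted p = 7.37e-09; adjusted p = 0.464 with an estimated correlation). The complement gene C1qc, made by macrophages, was at 28.0 ± 26.1 TPM in CAC and 8.60 ± 4.47 TPM in Con (SD, n = 5; adjusted p = 0.0782). The immunoglobulin gene Ighm was at 45.9 ± 21.9 and 92.9 ± 32.7 TPM (adjusted p = 0.336), and both tested lymphocyte genes fell when adjusted over the list alone (adjusted p = 0.0226 with an estimated correlation). Lists of the extracellular matrix and of fibroblasts stood higher by camera (adjusted p = 0.000178 and 0.00429), with adjusted p = 0.922 and 0.825 with an estimated correlation. Those of fatty acid oxidation, the mitochondrial genome, slow sarcomere and proteasome stood lower (adjusted p = 0.000178, 0.00686, 0.0116 and 0.0437), with adjusted p = 0.825 for the first and 0.922 for the others with an estimated correlation. The median change of the proteasome list was nevertheless 0.0132.

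In all, 35 genes were called at 2 weeks, 33 higher and 2 lower, and 30 after rescaling, 24 higher and 6 lower. The count was 16 without Con replicate 1, 18 without Con replicate 3, 114 without CAC replicate 1, 7 without CAC replicate 3, 10 without CAC replicate 4 and 70 without CAC replicate 5. Stat3, Socs3, Tmem176b and Atp9a were called in each of these refits, but Socs3, Tmem176b and Atp9a were not with the 2 groups fitted alone (adjusted p = 0.143, 0.121 and 0.108), where 2 genes were called. C4b was not called without CAC replicate 3 (adjusted p = 0.122) or replicate 4 (0.211). Aldh1a2 and Tmem176a each missed the threshold without CAC replicate 3 (0.106 for both) or replicate 4 (0.172 for both), and Aldh1a2 also without Con replicate 1 (0.0503). Cox7a2 was not called without CAC replicate 3 (adjusted p = 0.164) or 4 (0.332), without Con replicate 3 (0.0578), 4 (0.117) or 5 (0.0783), or with the 2 groups fitted alone (0.123). The Ndufs4 call was lost when any single library was left out, except Con replicate 2 or CAC replicate 1, with adjusted p up to 0.231, and with the 2 groups fitted alone (0.0958). With array weights 390 genes were called.

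At 4 weeks, several chemokine, STAT3 pathway and acute phase genes were higher in CAC muscle than in Con muscle. Ccl8, a chemokine that attracts monocytes, rose from 0.766 ± 0.317 to 41.6 ± 26.7 TPM (SD, n = 5), a log2 change of 4.38 (SE 0.780, adjusted p = 0.000117). Socs3 rose by 4.02 (SE 0.417, adjusted p = 9.06e-10) and Stat3 by 1.85 (SE 0.129, adjusted p = 6.86e-16). The acute phase genes Hp, which encodes haptoglobin, and Serpina3n, a protease inhibitor gene, rose by 3.44 and 3.13. The metallothionein genes Mt2 and Mt1, which bind zinc and respond to glucocorticoids, rose by 3.71 and 2.77. Ighm fell from 118 ± 43.7 to 19.6 ± 10.2 TPM (SD, n = 5; log2 change -2.61, adjusted p = 0.000308).

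Other large rises at 4 weeks were Wfdc17 (2.89), C4b (2.89) and the transcription factor gene Junb (2.52). The smooth muscle genes Myh11 and Cnn1 each fell by 1.07, and Metrn, which encodes the secreted factor meteorin, fell by 0.92. Crybb1, Rsph1, Dkk3 and Gkn3 fell by 1.17, 1.02, 0.94 and 0.91. Among the sentinel genes, the muscle ubiquitin ligase genes Trim63 (MuRF1) and Fbxo32 (atrogin-1) missed the threshold. Trim63 was at 600 ± 686 TPM in CAC and 182 ± 20.3 TPM in Con (adjusted p = 0.0871), and Fbxo32 at 286 ± 320 and 91.6 ± 20.9 TPM (adjusted p = 0.0854; SD, n = 5). Chrna1, the acetylcholine receptor subunit that rises on denervation, rose by 0.92 (adjusted p = 0.016).

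Of the 22 STAT3 and acute phase genes 14 rose and 8 were not called at 4 weeks, with 15 adjusted over the list alone and 13 after rescaling (camera adjusted p = 2.15e-08; adjusted p = 0.243 with an estimated correlation). Of 13 macrophage markers 12 rose, and 13 adjusted over the list alone, C1qc by 1.72 and the Fc receptor gene Fcgr3 by 1.32 (camera adjusted p = 1.36e-05; adjusted p = 0.59 with an estimated correlation). Of 81 nuclear oxidative phosphorylation genes 46 fell, 0 rose and 35 were not called, with 56 falls and 1 rise adjusted over the list alone and 63 falls after rescaling (camera adjusted p = 2.47e-43; adjusted p = 0.0889 with an estimated correlation). Cox5a fell by 0.41, Ndufa10 by 0.28 and Atp5g1 by 0.45. Of 13 genes of the mitochondrial genome 4 fell, also adjusted over the list alone, and 8 after rescaling, among them mt-Cytb, by 0.28 (camera adjusted p = 1.42e-09; adjusted p = 0.243 with an estimated correlation). Autophagy and lysosome genes rose in 9 of 22 cases, in 11 adjusted over the list alone and in 2 after rescaling, with Lamp2 up by 0.90 and Map1lc3b by 0.88 (camera adjusted p = 0.0356; adjusted p = 0.792 with an estimated correlation). Ribosomal protein genes rose in 33 of 77 cases, and in 60 adjusted over the list alone (camera adjusted p = 5.73e-05; adjusted p = 0.792 with an estimated correlation), but 0 of the 77 were called after rescaling. Of 12 Schwann cell genes 0 were called, 1 fell after rescaling, and the list stood below other genes, at a median of -0.48 (camera adjusted p = 2.65e-06; adjusted p = 0.505 with an estimated correlation).

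Camera also placed the 4 weeks lists of fatty acid oxidation, myokines, polyamine and creatine metabolism, adipocytes and lymphocytes below other genes. Their adjusted p values were 0.00703, 0.0175, 0.0392, 0.0379 and 0.00205. Fatty acid oxidation genes rose in 2 of 27 cases and in 0 adjusted over the list alone, while after rescaling 5 fell. Of 14 myokine genes 2 rose and 2 fell, with 2 and 5 adjusted over the list alone and 1 and 4 after rescaling. Of 12 polyamine genes 1 fell, also adjusted over the list alone, 0 of 13 adipocyte genes were called either way, and 1 of the 2 lymphocyte genes fell either way. With an estimated correlation the lymphocyte call held (adjusted p = 0.0294) and the other 4 did not (adjusted p = 0.792, 0.243, 0.141 and 0.792). The median change was above 0 in the first 4 of these lists, at 0.00318, 0.0225, 0.0515 and 0.0911. The mean was below 0 in the myokine, polyamine and adipocyte lists, at -0.0616, -0.0153 and -0.0291. Growth factor genes went both ways, with Igf1 and Mstn (myostatin) up by 0.67 and 0.64 and Apln (apelin) down by 0.72, and Mstn was not called after rescaling (adjusted p = 0.141).

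At 4 weeks 3134 genes were called, 2840 higher and 294 lower, and 1822 after rescaling, 935 higher and 887 lower. With the 2 groups fitted alone 1160 were called, and 1691 without mitochondrial genes. A single library carried much of this count, which was 758 without CAC replicate 2. Stat3, Socs3, Ccl8, Hp, Serpina3n, C4b, Wfdc17, Junb, Ighm, Lamp2 and Map1lc3b were called without it. Chrna1 (adjusted p = 0.0785), Apln (0.0587), Igf1 (0.106), Mstn (0.159), Dkk3 (0.131) and mt-Cytb (0.115) were not.

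At 6 weeks, the largest rises of CAC from Con were in metallothionein and acute phase genes. Mt2 rose from 21.7 ± 9.09 to 2071 ± 1876 TPM (SD, n = 5), a log2 change of 6.21 (SE 0.842, adjusted p = 2.12e-07). Hp rose by 5.13, Mt1 by 5.11, Serpina3n by 4.73 and Lcn2, the acute phase lipocalin gene, by 4.33. Trim63 rose from 165 ± 8.45 to 882 ± 771 TPM (log2 change 2.02, SE 0.504, adjusted p = 0.000981) and Fbxo32 from 97.4 ± 15.9 to 413 ± 245 TPM (log2 change 1.90, SE 0.489, adjusted p = 0.00127; SD, n = 5). Actc1, the cardiac actin gene also expressed in developing and regenerating muscle, fell by 3.39 (SE 0.657, adjusted p = 6.81e-05).

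Among the other rises at 6 weeks were Socs3 (4.16), the chemokine genes Ccl8 (3.78) and Cxcl13 (3.41) and the glucocorticoid target Fkbp5 (2.78). The growth arrest genes Cdkn1a and Gadd45a rose by 1.49 and 1.37. Foxo1, a transcription factor of the fasting response, rose by 1.17 (adjusted p = 0.012), but not after rescaling (0.0788) or without CAC replicate 1 (0.0904). Falls included Ostn (-2.91), the gene of the myokine osteocrin, and Chad (-2.72), Nrep (-2.37), Ighm (-1.92), Dupd1 (-1.80) and the myosin binding protein gene Mybph (-2.06). The Mybph call was lost without CAC replicate 1 (adjusted p = 0.0778). Nnat fell by 1.90, but not without CAC replicate 1 (adjusted p = 0.057) or Con replicate 5 (0.0748). Pdk4, which holds back the entry of pyruvate into mitochondria, was at 657 ± 253 TPM in CAC and 308 ± 129 TPM in Con (SD, n = 5; adjusted p = 0.063).

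Of 14 ubiquitin ligases of atrophy 6 rose, 1 fell and 7 were not called at 6 weeks, also adjusted over the list alone, and 4 rose and 3 fell after rescaling. Their median was 0.226 against 0.275 for all genes (camera adjusted p = 0.853). By 6 weeks 16 of 17 glucocorticoid response genes had risen, all 17 adjusted over the list alone and 11 after rescaling (camera adjusted p = 0.00252; adjusted p = 0.579 with an estimated correlation). Of the 22 STAT3 and acute phase genes 19 rose, also adjusted over the list alone, and 17 after rescaling, with the oncostatin M receptor gene Osmr up by 1.85 (camera adjusted p = 1.42e-09; adjusted p = 0.185 with an estimated correlation). Proteasome genes rose in 31 of 37 cases, and in 33 adjusted over the list alone, Psmd4 by 1.07 (camera adjusted p = 2.98e-05; adjusted p = 0.57 with an estimated correlation), but in 7 after rescaling. Ribosomal protein genes rose in 74 of 77 cases, also adjusted over the list alone, Rps9 by 0.70 (camera adjusted p = 2.66e-14; adjusted p = 0.477 with an estimated correlation), and in 43 after rescaling, with 1 fall. Of 20 genes of ribosome assembly and translation 14 rose, 15 adjusted over the list alone and 5 after rescaling, Myc by 1.69 and the elongation factor gene Eef2 by 1.05 (camera adjusted p = 0.035; adjusted p = 0.701 with an estimated correlation). Autophagy and lysosome genes rose in 20 of 22 cases, also adjusted over the list alone, Ctsd by 0.92 (camera adjusted p = 0.00112; adjusted p = 0.56 with an estimated correlation), and in 8 after rescaling. Macrophage markers rose in 11 of 13 cases, in 12 adjusted over the list alone and in 10 after rescaling, Cd163 by 1.85 and Cd14 by 1.20 (camera adjusted p = 0.0166; adjusted p = 0.701 with an estimated correlation).

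Of 81 nuclear oxidative phosphorylation genes 56 fell, 6 rose and 19 were not called at 6 weeks, also adjusted over the list alone, and 74 fell and 0 rose after rescaling (camera adjusted p = 3.84e-37; adjusted p = 0.125 with an estimated correlation). The complex I gene Ndufs1 fell by 0.68 and the complex III gene Uqcrc2 by 0.37, while Atp5g2 rose by 0.39 (0.07 after rescaling, not called). Of 13 genes of the mitochondrial genome 12 fell, also adjusted over the list alone, mt-Co2 by 0.49 (camera adjusted p = 5.85e-18; adjusted p = 0.125 with an estimated correlation). Fatty acid oxidation genes fell in 8 of 27 cases and rose in 3, with 8 and 2 adjusted over the list alone and 15 and 0 after rescaling, and Acads and Hadha fell by 0.55 and 0.46 (camera adjusted p = 1.23e-09; adjusted p = 0.215 with an estimated correlation). Of 15 fast sarcomere genes 6 fell and 3 rose, with 6 and 4 adjusted over the list alone (camera adjusted p = 0.000362; adjusted p = 0.204 with an estimated correlation). Their median was 0.0288 and their mean -0.195, and after rescaling 7 fell and 0 rose. The calcium-binding genes Casq1 and Pvalb fell by 1.62 and 1.08, and the myosin light chain gene Mylpf by 0.68. Myh4, the main myosin heavy chain of fast fibres, was at 13740 ± 2061 TPM in CAC and 13510 ± 2341 TPM in Con (SD, n = 5; adjusted p = 0.863).

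Lists of glycolysis, interferon response, myokines, polyamines, erythroid cells and lymphocytes also stood below other genes at 6 weeks (camera adjusted p = 0.00836, 0.035, 0.00112, 0.0413, 0.000889 and 0.035). These calls were lost, with adjusted p = 0.398, 0.718, 0.125, 0.126, 0.26 and 0.126 with an estimated correlation. Glycolysis genes rose in 7 and fell in 7 of 20 cases, with 8 and 7 adjusted over the list alone and 2 and 9 after rescaling, Gpi1 rising by 0.72 and Pgm2 falling by 0.85, and their median (0.146) and mean (0.0185) were above 0. The medians of the interferon, myokine and polyamine lists were also above 0, at 0.145, 0.0625 and 0.148. Sat1, which breaks down polyamines, rose by 1.32 and the mitochondrial creatine kinase gene Ckmt2 fell by 0.71. In the erythroid list Bpgm fell by 0.82 and the other 6 genes were not called. Interferon genes rose in 3 and fell in 1 of 21 cases, with 2 and 0 adjusted over the list alone and 2 and 1 after rescaling. Myokine genes rose in 2 and fell in 5 of 14, also adjusted over the list alone, and after rescaling 2 rose and 7 fell. Polyamine genes rose in 5 and fell in 4 of 12 cases, with 6 and 4 adjusted over the list alone, and after rescaling 2 rose and 5 fell.

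At 6 weeks 7069 genes were called, 6400 higher and 669 lower, and 3866 after rescaling, 1771 higher and 2095 lower. Without mitochondrial genes 4600 were called. The count was between 5523 and 7186 when each library was left out.

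At 8 weeks, the largest changes from Con were again in metallothionein and acute phase genes. Mt2, on chromosome 8 from 94172664 to 94173568, was at 2331 ± 1300 TPM in CAC (SD, n = 7) and 13.4 ± 5.58 TPM in Con (SD, n = 5), a fold of 116 on TPM + 1 (log2 change 6.86, SE 0.780, adjusted p = 1.13e-09). Serpina3n, on chromosome 12 from 104406729 to 104414329, was at 281 ± 153 and 4.06 ± 1.43 TPM (log2 change 5.46, SE 0.522, adjusted p = 1.18e-11). Trim63, on chromosome 4 from 134315120 to 134329629, was at 1121 ± 1215 and 151 ± 11.1 TPM (log2 change 2.03, SE 0.467, adjusted p = 0.000185). Fbxo32 was at 379 ± 348 and 84.3 ± 6.01 TPM (log2 change 1.46, SE 0.453, adjusted p = 0.00389). Actc1 fell from 449 ± 166 to 76.4 ± 103 TPM (log2 change -3.61, SE 0.608, adjusted p = 2.16e-06). CAC replicate 3 stood apart from the other 6 libraries of its group, with Mt2 at 82.0 TPM against 1378 to 3944 TPM and Fkbp5 at 8.79 TPM against 87.6 to 201 TPM.

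Other large rises at 8 weeks were Mt1 (5.76), Hp (4.84), Lcn2 (4.80), Cxcl13 (4.34), the mTORC1 inhibitor gene Ddit4 (4.20), Ccl8 (4.08) and Socs3 (3.97). Among the sentinel genes, Fkbp5 rose by 3.13, Foxo1 by 1.90, Gadd45a by 1.70, Chrna1 by 1.67 and Cdkn1a by 1.63. Pdk4 rose by 1.24, Fbxo30 by 0.63 and the slow myosin gene Myh7 by 0.59, but none of them was called after rescaling (adjusted p = 0.144, 0.253 and 0.615). Large falls were Ighm (-3.16), Ostn (-2.85), Nmrk2 (-2.33), which serves NAD synthesis, Nrep (-2.08), Chad (-1.995), Nnat (-1.99) and Mettl21e (-1.77). Myh4 was at 11530 ± 2174 TPM in CAC (SD, n = 7) and 12500 ± 740.5 TPM in Con (SD, n = 5; adjusted p = 0.303), and after rescaling it fell by 0.56 (adjusted p = 0.00115). The collagen genes Col1a1 and Col3a1 were not called (adjusted p = 0.928 and 0.916), nor were the muscle differentiation gene Myog (0.168) and the mitochondrial coactivator gene Ppargc1a (0.333).

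Of all 12364 tested genes 8069 were called higher at 8 weeks, so that high counts in a list do not by themselves set it apart, and camera did not call the ubiquitin ligase and proteasome lists. Of 14 ubiquitin ligases of atrophy 11 rose and 2 fell, also adjusted over the list alone, and 5 rose and 3 fell after rescaling (camera adjusted p = 0.938). Proteasome genes rose in 29 of 37 cases, also adjusted over the list alone, but after rescaling 2 rose and 7 fell (camera adjusted p = 0.195). Autophagy and lysosome genes rose in 21 of 22 cases, and in 22 adjusted over the list alone, Lamp2 by 1.07, Gabarap by 0.86 and Map1lc3b by 1.35 (camera adjusted p = 0.0079; adjusted p = 0.709 with an estimated correlation). After rescaling 9 of these rose and 1 fell. FoxO and fasting genes rose in 12 of 16 cases, also adjusted over the list alone, and 9 rose and 1 fell after rescaling (camera adjusted p = 0.237). All 17 glucocorticoid response genes rose, also adjusted over the list alone, and 15 after rescaling (camera adjusted p = 0.000826; adjusted p = 0.644 with an estimated correlation).

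All 22 STAT3 and acute phase genes rose at 8 weeks, also adjusted over the list alone, and 20 after rescaling, with Stat3 up by 1.88 and Osmr by 1.97 (camera adjusted p = 1.93e-08; adjusted p = 0.213 with an estimated correlation). Interferon response genes rose in 7 of 21 cases and in 3 adjusted over the list alone, but after rescaling 2 rose and 4 fell (camera adjusted p = 0.0531). Immediate early genes rose in 13 of 17 cases, and in 10 after rescaling (camera adjusted p = 0.145). Endoplasmic reticulum stress genes rose in 16 of 20 cases, and in 3 after rescaling (camera adjusted p = 0.561). Heat shock genes rose in 15 of 19 cases, but after rescaling 3 rose and 3 fell (camera adjusted p = 0.938). Circadian clock genes rose in 8 and fell in 2 of 17 cases, and after rescaling 2 rose and 3 fell (camera adjusted p = 0.0712). In these last 4 lists the counts were the same when adjusted over the list alone.

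Of 81 nuclear oxidative phosphorylation genes 62 fell, 5 rose and 14 were not called at 8 weeks, with 63 and 5 adjusted over the list alone, and 76 fell and 1 rose after rescaling. The list stood below other genes (camera adjusted p = 5.99e-51; adjusted p = 0.0221 with an estimated correlation). Ndufs1 fell from 218.5 ± 11.7 to 127 ± 24.5 TPM (log2 change -0.80, SE 0.101, adjusted p = 1.39e-08), and Uqcrc2 and Uqcrc1 fell by 0.50 and 0.64. Of 13 genes of the mitochondrial genome 12 fell, also adjusted over the list alone, and 13 after rescaling, with mt-Co3 falling by 0.57 (camera adjusted p = 1.22e-20; adjusted p = 0.0221 with an estimated correlation). Fatty acid oxidation genes fell in 9 and rose in 5 of 27 cases, with 8 and 4 adjusted over the list alone and 15 and 3 after rescaling (camera adjusted p = 4.04e-08; adjusted p = 0.283 with an estimated correlation). Their median was -0.0693 and their mean 0.0493, with Acads falling by 0.64 and the uncoupling protein gene Ucp2 and the fatty acid transporter gene Cd36 rising by 1.29 and 0.77. Glycolysis genes fell in 8 and rose in 6 of 20 cases, also adjusted over the list alone, Pkm falling by 0.53 and Pgm1 rising by 0.88 (camera lower, adjusted p = 0.000654; adjusted p = 0.233 with an estimated correlation). The median of that list was 0.0722 and its mean 0.0324, and after rescaling 13 fell and 1 rose. Gpi1 rose by 0.63, but was not called after rescaling (adjusted p = 0.128).

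Structural lists were mixed at 8 weeks. Of 15 fast sarcomere genes 6 fell and 5 rose, also adjusted over the list alone, and 9 fell and 0 rose after rescaling (camera adjusted p = 1.03e-05; adjusted p = 0.0859 with an estimated correlation). Myl1 and Pvalb fell by 0.90 and 1.07, while the calcium pump gene Atp2a1 rose by 0.47 (0.05 after rescaling, adjusted p = 0.743). Slow sarcomere genes rose in 6 of 13 cases and in 3 adjusted over the list alone, but after rescaling 1 rose and 1 fell (camera adjusted p = 0.167). Denervation and regeneration genes rose in 7 and fell in 2 of 16 cases, also adjusted over the list alone, and after rescaling 4 rose and 3 fell (camera adjusted p = 0.195). Extracellular matrix genes rose in 10 of 30 cases, also adjusted over the list alone, and after rescaling 6 rose and 5 fell. The collagen cross-linking gene Lox rose by 2.63 and the matrix protease genes Mmp14 and Mmp2 by 1.55 and 0.88. Camera placed this list below other genes although its median (0.147) and mean (0.349) were above 0 (adjusted p = 0.0204; adjusted p = 0.775 with an estimated correlation).

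Ribosomal protein genes rose in 76 of 77 cases at 8 weeks, also adjusted over the list alone, and after rescaling 64 rose and 1 fell, with Rps9 up by 0.87 and Rps28 by 0.94 (camera adjusted p = 3.32e-15; adjusted p = 0.534 with an estimated correlation). Of 20 genes of ribosome assembly and translation 17 rose, also adjusted over the list alone, but 7 rose and 5 fell after rescaling (camera adjusted p = 0.146). Myokine genes rose in 5 and fell in 5 of 14 cases, also adjusted over the list alone, and 3 rose and 6 fell after rescaling, with Igfbp3 and Igf1 rising by 1.63 and 1.06 (camera lower, adjusted p = 0.00103; adjusted p = 0.0765 with an estimated correlation). The median of that list was 0.118 and its mean -0.064. Polyamine and creatine genes fell in 5 and rose in 4 of 12 cases, with 5 and 5 adjusted over the list alone and 6 and 2 after rescaling (camera lower, adjusted p = 0.000401; adjusted p = 0.0044 with an estimated correlation). Their median was -0.0543 and their mean 0.00303. Sat1 rose by 1.45, while Ckmt2 fell by 1.00 and the spermine synthase gene Sms by 0.37.

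Lists of markers of other cell types differed in their counts at 8 weeks, and camera called only that of lymphocytes, which fell. All 13 macrophage markers rose, also adjusted over the list alone, and 10 after rescaling (camera adjusted p = 0.0698). Of 11 endothelial markers 10 rose and 1 fell, also adjusted over the list alone, and 7 rose and 1 fell after rescaling (camera adjusted p = 0.0684). Fibroblast markers rose in 8 of 12 cases, and in 5 after rescaling (camera adjusted p = 0.72). Satellite cell markers rose in 6 of 11, and after rescaling 4 rose and 1 fell (camera adjusted p = 0.72). Neutrophil markers rose in 4 of 5, and in 3 after rescaling (camera adjusted p = 0.401). Adipocyte markers rose in 7 and fell in 1 of 13, and after rescaling 4 rose and 2 fell (camera adjusted p = 0.254). Schwann cell markers rose in 1 of 12 (camera adjusted p = 0.183), melanocyte and tumour markers in 2 of 4 (0.909) and proliferation markers in 1 of 5 (0.237). The 2 melanocyte genes were Mitf (0.46) and Gpnmb (1.43), which macrophages also express, and both were named after their values were seen. The counts of these last 7 lists were the same when adjusted over the list alone. After rescaling 1 melanocyte gene rose, and 1 proliferation gene rose and 1 fell. Erythroid genes rose in 1 of 7 cases and in 0 adjusted over the list alone, and after rescaling 0 rose and 1 fell (camera adjusted p = 0.0577). Of the 2 tested lymphocyte genes Ighm fell and Igkc was not called, also adjusted over the list alone (camera adjusted p = 0.000821; adjusted p = 0.00865 with an estimated correlation).

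At 8 weeks 8755 genes were called, 8069 higher and 686 lower, and 5517 after rescaling, 2723 higher and 2794 lower. Changes over 2-fold were called in 706 genes higher and 69 lower, and after rescaling in 292 and 158. The count was between 8090 and 9002 when each library was left out, and 9044 without CAC replicate 3 and NCAC replicate 3, a setting chosen after seeing the data.

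**Figure D2:**
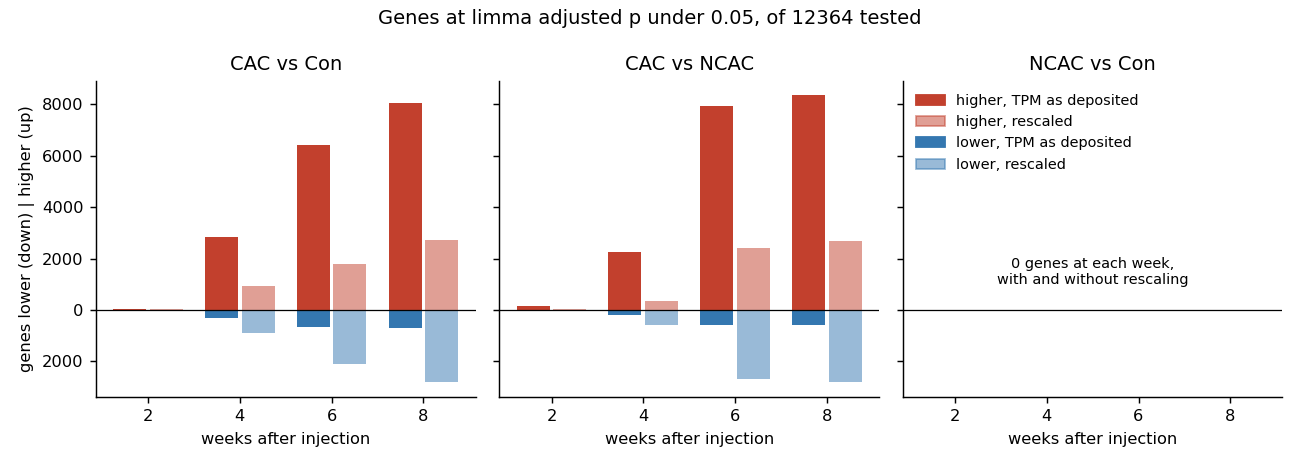
Number of genes called higher (upward bars) and lower (downward bars) at an adjusted p under 0.05 in limma, against weeks after injection, for each comparison, from TPM as deposited (dark) and after rescaling (light). In CAC against Con at 8 weeks 8069 genes were higher and 686 lower, and after rescaling 2723 and 2794, so that the direction split depends on the scaling.

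**Figure D3:**
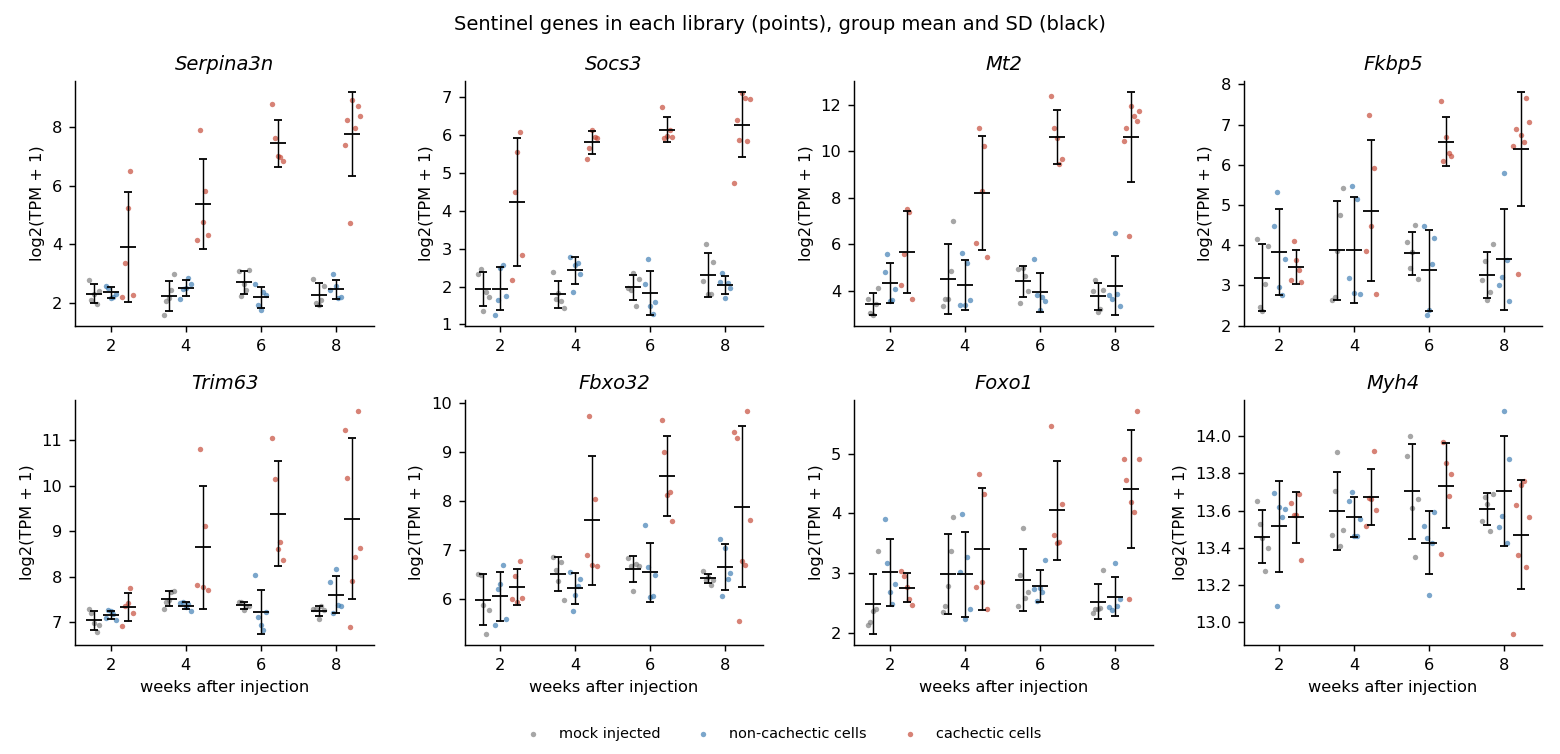
Level of 8 sentinel genes as log2(TPM + 1) in each library (points), with the group mean and SD (black), against weeks after injection. At 8 weeks Serpina3n was at 281 TPM on average in mice with cachectic cells and at 4.06 TPM in mock-injected mice.

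Calls of CAC against Con were shared between weeks, in numbers that depended on the scaling. Of the 33 genes higher at 2 weeks, 31 were higher at 4 weeks, where 7.58 would be shared by chance. Of the 2840 higher at 4 weeks 2384 were higher at 6 weeks (1470 by chance), and of the 294 lower 204 were lower (15.9 by chance). Between 6 and 8 weeks 6107 higher and 487 lower calls were shared (4180 and 37.1 by chance). The numbers by chance assume independent calls. All weeks used the same SD of a gene, so genes of low spread tend to be called together, and these numbers may be too low. After rescaling, 23 of the 24 genes higher at 2 weeks were higher at 4 weeks, 483 of the 935 higher and 685 of the 887 lower at 4 weeks were so at 6 weeks, and 1511 higher and 1810 lower calls were shared between 6 and 8 weeks. Across genes, which are not independent replicates, the changes at 6 and 8 weeks correlated at 0.901 and those at 2 and 8 weeks at 0.519.

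The test across weeks asked whether the difference between CAC and Con changed with time. Serpina3n (adjusted p = 0.00535) and Mt2 (0.0161) differed between weeks, with Serpina3n at log2 changes of 1.59, 3.13, 4.73 and 5.46 and Mt2 at 2.23, 3.71, 6.21 and 6.86 at 2, 4, 6 and 8 weeks. The lowest p values were those of Scgb3a1, a secretoglobin gene, at 0.38, 1.24, 2.18 and 2.67 (adjusted p = 0.00026), and of Kbtbd12 (0.23, 0.23, 0.05 and -0.39; adjusted p = 0.00026). Tagln, an actin-binding gene of smooth muscle, was at -0.20, -0.53, 1.29 and 1.62 (adjusted p = 0.000465). Grrp1 (adjusted p = 0.00075), Sema6b (0.00188), Cxcl13 (0.00212), Myrip (0.00212) and Rpl22l1 (0.00212) followed. Trim63 (adjusted p = 0.153), Fbxo32 (0.257), Foxo1 (0.0807), Fkbp5 (0.0532) and Socs3 (0.0521) were not shown to change between weeks.

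In this test 1497 genes were called, 527 after rescaling, 402 without mitochondrial genes and 269 with only the groups compared. The count was 854 without Con 2 weeks replicate 4, 748 without Con 8 weeks replicate 4, 665 without CAC 2 weeks replicate 1, 861 without CAC 2 weeks replicate 2, 3109 without CAC 4 weeks replicate 2 and 3143 without CAC 8 weeks replicate 3.

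The comparison of CAC with NCAC asked what differed between muscle of mice with cachectic and with non-cachectic melanoma cells. At 2 weeks Stat3 was at 30.6 ± 8.22 TPM in CAC and 11.2 ± 0.783 TPM in NCAC (SD, n = 5), a log2 difference of 1.34 (SE 0.129, adjusted p = 2e-10). Socs3 was higher by 2.28, C4b by 1.89, Junb by 1.61, complement C3 by 1.43 and Tmem176b by 1.37. Wfdc17 (2.11) and the mechanosensitive channel gene Piezo1 (1.34) were also higher, while Mtus1 was lower (-0.41), and Wfdc17 and C3 were not called after rescaling (adjusted p = 0.0907 and 0.0701). STAT3 and acute phase genes were higher in 5 of 22 cases, and in 12 adjusted over the list alone (camera adjusted p = 5.89e-06; adjusted p = 0.456 with an estimated correlation). Extracellular matrix genes were higher in 1 of 30 cases, Mmp14 (adjusted p = 0.0434; 0.0873 after rescaling), in 10 adjusted over the list alone and in 0 after rescaling (camera adjusted p = 0.00015; adjusted p = 0.618 with an estimated correlation). Macrophage markers were called in 0 of 13 cases, and in 11 adjusted over the list alone (camera adjusted p = 1.28e-05; adjusted p = 0.456 with an estimated correlation).

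Camera placed 11 lists below other genes at 2 weeks. These were those of the glucocorticoid response, nuclear oxidative phosphorylation, the mitochondrial genome, fatty acid oxidation, slow sarcomere, heat shock, the clock, immediate early genes, erythroid cells, neutrophils and lymphocytes, of which 0 held with an estimated correlation, the lowest being adjusted p = 0.195.

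At 2 weeks 145 genes were called, 143 higher and 2 lower, and 57 after rescaling, 44 higher and 13 lower. With the 2 groups fitted alone 94 were called, and 52 without mitochondrial genes. The count was 47, 69, 81 and 41 without NCAC replicates 1, 2, 4 and 5, and 257, 417, 26 and 14 without CAC replicates 1, 2, 3 and 4. Without CAC replicate 3 or 4 the calls of C4b (adjusted p = 0.0777 and 0.191), Junb (0.0602 and 0.164) and Piezo1 (0.0805 and 0.164) were lost. Those of Mtus1 (0.0864 and 0.344), Wfdc17 (0.141 and 0.407) and C3 (0.121 and 0.355) were lost there too, and also when any single NCAC library was left out. With the 2 groups fitted alone, Stat3 was called, but Socs3 (adjusted p = 0.0837) and Tmem176b (0.0676) were not.

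At 4 weeks Mt2 was at 739 ± 886 TPM in CAC and 22.9 ± 18.3 TPM in NCAC (SD, n = 5; log2 difference 3.96, SE 0.842, adjusted p = 0.00168). Ccl8 was higher by 3.63, Socs3 by 3.38, Mt1 by 2.98, Serpina3n by 2.85, Hp by 2.82, Junb by 2.46 and Wfdc17 by 2.36. Fbxo32 was higher by 1.40 (adjusted p = 0.0408; 0.11 after rescaling) and Trim63 was not called (adjusted p = 0.0612). Ighm was lower (-2.22), as were Actc1 (-2.04), Tceal7 (-1.42) and Chad (-1.55; adjusted p = 0.0557 after rescaling). STAT3 and acute phase genes were higher in 13 of 22 cases and lower in 1, with 14 and 1 adjusted over the list alone and 12 and 1 after rescaling (camera adjusted p = 7.42e-06; adjusted p = 0.54 with an estimated correlation). The lower one was Fgg, a fibrinogen gene made in liver, at -0.94 (adjusted p = 0.0318), named after its value was seen. Autophagy and lysosome genes were higher in 11 of 22 cases, in 13 adjusted over the list alone and in 2 after rescaling (camera adjusted p = 0.005; adjusted p = 0.723 with an estimated correlation). Macrophage markers were higher in 6 of 13 cases, in 10 adjusted over the list alone and in 2 after rescaling (camera adjusted p = 0.00848; adjusted p = 0.723 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower in 17 of 81 cases, and lower in 21 and higher in 1 adjusted over the list alone and lower in 43 after rescaling, Atp5g1 at -0.51 (camera adjusted p = 1.18e-32; adjusted p = 0.156 with an estimated correlation).

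At 4 weeks 2435 genes were called, 2238 higher and 197 lower, and 954 after rescaling, 364 higher and 590 lower. With the 2 groups fitted alone 431 were called, and 768 without mitochondrial genes. The count was 274 without CAC replicate 2, and 1273, 897 and 1228 without NCAC replicates 1, 3 and 4. Without CAC replicate 2, Hp (adjusted p = 0.125), Fbxo32 (0.315), Actc1 (0.223) and Tceal7 (0.0527) were not called.

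At 6 weeks Mt2 was at 2071 ± 1876 TPM in CAC and 16.9 ± 13.2 TPM in NCAC (SD, n = 5; log2 difference 6.68, SE 0.842, adjusted p = 2.13e-08). Hp was higher by 5.78, Serpina3n by 5.23, Lcn2 by 4.49 and Cebpd, a transcription factor gene of the acute phase response, by 3.85. Trim63 and Fbxo32 were higher by 2.16 and 1.97 (adjusted p = 0.00024 and 0.000508), and Cdkn1a by 2.06. Actc1 (-3.73), Chad (-2.70), Ighm (-2.49), Nrep (-2.46) and Ostn (-2.21) were lower. All 13 genes of the mitochondrial genome were lower, also adjusted over the list alone, mt-Nd3 at -0.96 (camera adjusted p = 1.09e-26; adjusted p = 0.0167 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower in 51 of 81 cases and higher in 5, also adjusted over the list alone, and after rescaling 75 were lower and 0 higher (camera adjusted p = 2.36e-40; adjusted p = 0.0588 with an estimated correlation). Of 12 polyamine and creatine genes 4 were higher and 4 lower, also adjusted over the list alone, and after rescaling 2 were higher and 5 lower (camera lower, adjusted p = 0.0104; adjusted p = 0.0477 with an estimated correlation), although their median was 0.103 and their mean 0.131. The lymphocyte list stood lower (camera adjusted p = 0.00485; adjusted p = 0.0432 with an estimated correlation). Ribosomal protein genes were higher in 75 of 77 cases, and in 76 adjusted over the list alone, and after rescaling 56 were higher and 1 lower, Rps27 by 1.27 (camera adjusted p = 5.04e-16; adjusted p = 0.499 with an estimated correlation). Myh4 was higher by 0.30 (adjusted p = 0.0352), Aldoa by 0.45, Gys1 by 0.44 and Eif4g1 by 0.42, but after rescaling these were at -0.15, -0.00472, -0.0126 and -0.0313.

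At 6 weeks 8500 genes were called, 7926 higher and 574 lower, and 5084 after rescaling, 2394 higher and 2690 lower. The range when each library was left out was 7717 to 8526.

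At 8 weeks Mt2 was at 2331 ± 1300 TPM in CAC (SD, n = 7) and 26.9 ± 34.0 TPM in NCAC (SD, n = 5; log2 difference 6.40, SE 0.780, adjusted p = 5.12e-09). NCAC replicate 3 held 87.7 TPM of it, against 9.06 to 13.3 TPM in the other 4 libraries of that group. Serpina3n was higher by 5.27, Ccl8 by 4.73, Socs3 by 4.23, Chrna1 by 1.81 and Foxo1 by 1.81. Trim63 was higher by 1.67 (adjusted p = 0.00146) and Fbxo32 by 1.23 (adjusted p = 0.0139; 0.142 after rescaling). Ighm (-3.58), Actc1 (-3.41), Mettl21e (-2.12), the cadherin gene Cdh4 (-1.94) and Ostn (-1.89) were lower. Nuclear oxidative phosphorylation genes were lower in 57 of 81 cases and higher in 6, with 58 and 6 adjusted over the list alone and 76 and 1 after rescaling (camera adjusted p = 4.28e-48; adjusted p = 0.0247 with an estimated correlation). Fast sarcomere genes were lower in 6 and higher in 4 of 15 cases, also adjusted over the list alone, and in 10 and 1 after rescaling, Myl1 at -0.91 and Tnnc2 at -0.47 (camera adjusted p = 4.82e-08; adjusted p = 0.0247 with an estimated correlation). Of 12 polyamine and creatine genes 5 were lower and 4 higher, also adjusted over the list alone, and 7 and 2 after rescaling, with a median of -0.0716 and a mean of 0.00443 (camera lower, adjusted p = 7.81e-05; adjusted p = 0.00119 with an estimated correlation). Macrophage markers were higher in 13 of 13 cases, also adjusted over the list alone, and in 11 after rescaling, Cd163 by 2.48 (camera adjusted p = 0.0111; adjusted p = 0.726 with an estimated correlation). Endothelial markers were higher in 9 of 11 cases, also adjusted over the list alone, and after rescaling 6 were higher and 1 lower, Esam by 1.32 and Pecam1 by 1.18 (camera adjusted p = 0.0456; adjusted p = 0.726 with an estimated correlation).

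At 8 weeks 8939 genes were called, 8346 higher and 593 lower, and 5499 after rescaling, 2681 higher and 2818 lower. The count was between 8357 and 9141 when each library was left out, and 8827 without the pair of libraries that stood apart.

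The comparison of NCAC with Con asked whether melanoma cells that do not cause cachexia changed the muscle. Limma called 0 genes at each of 2, 4, 6 and 8 weeks, and 0 after rescaling. At an unadjusted p under 0.05 there were 471, 224, 909 and 139 genes, and voom on the recovered reads also called 0 at each week. The lowest adjusted p was 0.881, 0.937, 0.624 and 1 in turn. By chance a share of 0.05 of the tested genes would have an unadjusted p under 0.05. Fewer were found at 2, 4 and 8 weeks, and more at 6 weeks. The model used 1 SD per gene over all groups, CAC included. Where Con and NCAC libraries spread less than that, the test is too strict, so 0 calls do not show that nothing changed. A fit of the Con and NCAC libraries only, added after seeing the data, also called 0 at each week. At 8 weeks Trim63 was at 200 ± 59.6 TPM in NCAC and 151 ± 11.1 TPM in Con, Serpina3n at 4.70 ± 1.35 and 4.06 ± 1.43 TPM, and Stat3-induced Socs3 at 3.18 ± 0.706 and 4.28 ± 2.21 TPM (SD, n = 5). At 4 weeks 18 genes were called without NCAC replicate 1 and 15 without NCAC replicate 5. At 2 weeks 17 were called with array weights.

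Camera called lists in NCAC against Con at each week, although 0 of their genes were called, and 0 of these calls held with an estimated correlation, the lowest being adjusted p = 0.123. At 2 weeks the glucocorticoid list stood higher, at a median of 0.54 (camera adjusted p = 2.56e-12, or 0.696 with an estimated correlation). It did so again at 8 weeks, at 0.40 (camera adjusted p = 2.19e-08, or 0.939 with an estimated correlation). There the glucocorticoid target Fkbp5 was at 54.5 TPM in NCAC replicate 3 and at 5.14 to 11.4 TPM in the other NCAC libraries. In Con it was at 5.20 to 15.5 TPM, so a single library may carry part of the rise at 8 weeks. At 4 weeks macrophage markers stood higher, at a median of 0.38 (camera adjusted p = 5.06e-06; adjusted p = 0.704 with an estimated correlation), and at 8 weeks lower, at -0.27 (camera adjusted p = 0.0101; adjusted p = 0.939 with an estimated correlation). At 6 weeks genes of the mitochondrial genome stood higher, at a median of 0.11, with 1 called when adjusted over the list alone (camera adjusted p = 5.99e-16; adjusted p = 0.123 with an estimated correlation). The nuclear oxidative phosphorylation list stood higher at 6 weeks by camera although its median was -0.0138 and its mean -0.0123 (adjusted p = 3.49e-05; adjusted p = 0.873 with an estimated correlation). The test across weeks called 0 genes for NCAC (186 at an unadjusted p under 0.05; 0 with voom).

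The changes of CAC and of NCAC from the same Con libraries correlated across genes at 0.262, 0.342, -0.0131 and 0.188 at 2, 4, 6 and 8 weeks. Sharing the controls alone gave 0.501, 0.5, 0.498 and 0.539 in data simulated without any effect. Real changes in CAC alone would lower r, so these values are not directly comparable with the observed ones. The observed covariances were 0.00882, 0.0154, -0.000921 and 0.0118, and the simulated ones 0.0156, 0.0156, 0.0155 and 0.0155. The simulation used 1 SD per gene over all 12 groups, CAC included. Where Con libraries spread less than that, the simulated covariances are too high, so they too are not directly comparable with the observed ones. With separate controls for each, the correlations were -0.0152, 0.093, -0.169 and 0.0486. These are correlations across genes, which are not independent replicates.

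**Figure D4:**
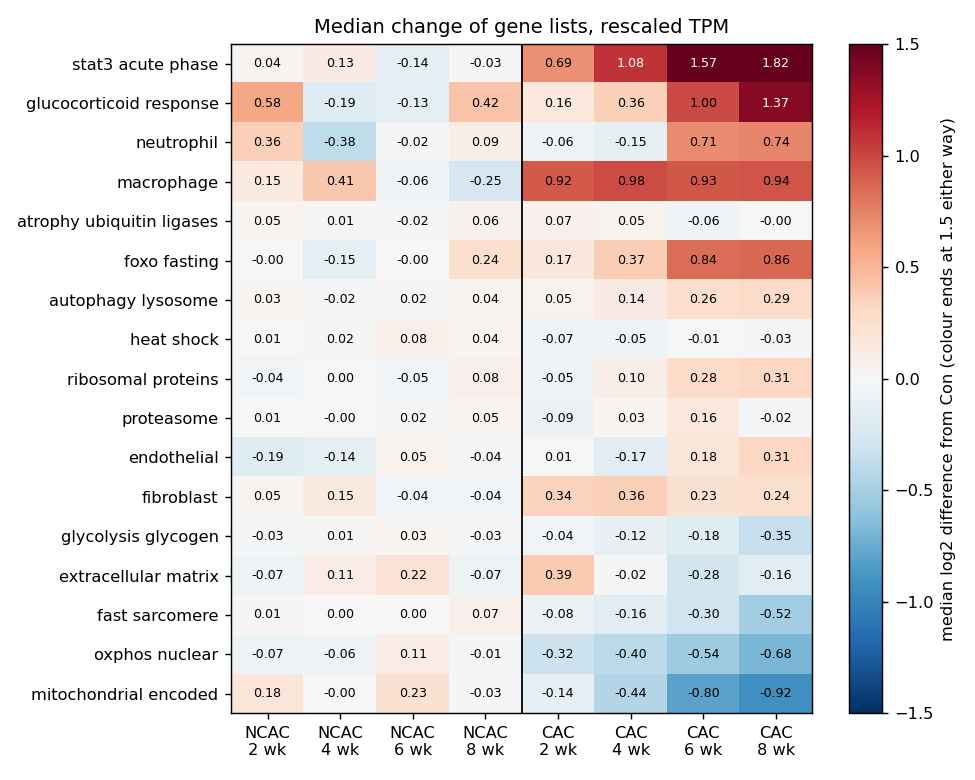
Median log2 difference from Con after rescaling (colour, with the value printed) of 17 gene lists, for NCAC (left) and CAC (right) at each week. The STAT3 and acute phase list of CAC stood at 0.69 at 2 weeks and 1.82 at 8 weeks, and the genes of the mitochondrial genome at -0.14 and -0.92.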

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

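Of the tests in this part, those of the 20 most abundant genes, of the mitochondrial share, of red blood cells, of sequencing depth, of a mixture and of the non-muscle markers were chosen only after the result was seen. Those of gene length, of a wrong label, of a swap and of the divisions of the libraries were set out before.

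More genes were called higher than lower in CAC against Con. With the 20 genes of highest mean TPM left out, 71.1% of the calls at 8 weeks were higher instead of 92.2%, so the share these genes take may account for part of the excess. A lower mitochondrial share as the whole cause was excluded, because 81.6% were higher without those genes. Among sets of genes by exon length, from shortest to longest, 86.4%, 91.3%, 94% and 95.8% of the calls were higher. The share thus rose with length, and length may account for part of the excess. The lowest of these values was 86.4%, but this could not exclude length as the whole cause. TPM is a share, so a loss in short abundant genes would raise the other genes in every set. After rescaling 49.4% of all calls were higher, but rescaling centres the ratios and so decides nothing here. Whether a fibre held less RNA in total was not tested.

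CAC replicate 3 at 8 weeks lay near the controls. Over 470 genes it scored 0.672, and the other 6 CAC libraries of 8 weeks scored 1.26 to 2.07. The 10 Con and NCAC libraries of 8 weeks scored -0.173 to 0.152. This excluded an 8-week control under a wrong label and, with 0.152 as the highest control, a swap with any of these 10. Libraries of other weeks were not compared in this way, so a wrong label or swap involving them stays open. Red cell genes held 1.80% of the TPM of replicate 3 and 0.0182% to 0.184% in the other CAC libraries, too little for dilution. Its depth of 45.51 M reads lay within 44.88 to 47.09 M in the others. At the CAC share that suited it best, 27.7% of the 470 genes lay outside what a mixture of CAC and control RNA allows, against 4.89% to 50% in the other CAC libraries, so a mixture stays possible, as do an earlier week and a slower disease course, which were not tested.

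Several lists of markers of non-muscle cells were higher in CAC at 8 weeks. A lower share of fibre RNA would move all marker lists about alike, apart from the damping of low TPM values by the + 1. After rescaling the macrophage list rose by 0.997 ± 0.309 (SE), 0.723 ± 0.209 (SE) more than the fibroblast list, and the endothelial list by 0.241 ± 0.0687 (SE). One joint test of 5 lists spoke against such a share as the whole cause (exact permutation p = 0.024). It was 1 of several tests chosen after the result, with no adjustment between them, so such a share stays possible. The lowest adjusted exact two-sided p among 10 pairs of these lists was 0.0725. Adding neutrophils gave 0.0063, but 0.109 without their gene shared with the STAT3 list. The erythroid list changed by -0.189 ± 0.698 (SE) after rescaling, which left blood open. In the 6 CAC libraries other than replicate 3 it changed by -0.765 ± 0.446 (SE) and the macrophage list by 1.03 ± 0.332 (SE). This argues against carried-over blood in those libraries only if the blood of CAC and Con mice held red and white cell RNA in the same ratio. That ratio was not measured.

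Each group was searched for a single library far from the rest in the 18 sentinel genes, where chance marks about 1 in 20. Of 216 tests 18 were marked, against 10.8 by chance. The number given is the gap to the nearest library as a share of the range. In CAC at 8 weeks, replicate 3 was lowest in Mt2 (0.728), Fkbp5 (0.727) and Serpina3n (0.64), and replicate 6 in Col1a1 (0.806). In NCAC at 8 weeks, replicate 3 was highest in Mt2 (0.837) and Foxo1 (0.765) and lowest in Col1a1 (0.761) and Col3a1 (0.876). Foxo1 was highest in Con replicate 5 at 2 weeks (0.787) and in Con replicate 5 at 8 weeks (0.88). Ppargc1a was highest in Con replicate 4 at 8 weeks (0.713) and NCAC replicate 3 at 6 weeks (0.806), where Gadd45a was lowest (0.839). Fbxo32 was lowest in Con replicate 3 at 6 weeks (0.76), Cdkn1a in NCAC replicate 1 at 4 weeks (0.747) and Myh4 in NCAC replicate 2 at 2 weeks (0.792). Socs3 was highest in CAC replicate 1 at 6 weeks (0.726) and Col3a1 in CAC replicate 5 at 4 weeks (0.715).

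The change of CAC from Con was called as differing between weeks in 1497 genes, among them Mt2 (adjusted p = 0.0161) and Serpina3n (0.00535). After rescaling 527 genes were called, and 269 with only the groups compared.

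The libraries were also divided at random into groups of the same sizes, 100 times per result, the real division included. In CAC against Con the real counts of 35, 3134, 7069 and 8755 were each the largest, with 13, 1303, 5068 and 8518 as the highest others. In CAC against NCAC the real 145, 2435, 8500 and 8939 were also each the largest, with 14, 333, 6772 and 8397 as the highest others, so 1 of 100 reached the real count in each of these 8. The median of the other divisions was 0 in each. The 8518 came from exchanging every Con library with CAC replicates 1, 2, 4, 6 and 7, and the 8397 from exchanging every NCAC library with CAC replicates 2, 3, 4, 6 and 7. Both are nearly the real division with its labels reversed. In NCAC against Con all 100 reached the real 0 at each week, with 0, 20, 2 and 2 as the highest others. Across weeks, 4 of 100 reached the 1497 of CAC, the highest other was 5583 and the median of the others was 0. These divisions exchanged CAC and Con libraries within each week. Where they reversed the labels more in 1 week than in another, the CAC difference itself became a change between weeks. They could therefore not decide whether the change across weeks arose by chance. For NCAC across weeks all 100 reached 0.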

How the results depend on the processing

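Refits used the alternatives described with the methods; voom, the length correction and the fit without both libraries apart were chosen after seeing the data. Leaving out each library gave 7–114, 758–3661, 5523–7186 and 8090–9002 calls in CAC against Con at 2, 4, 6 and 8 weeks and 14–417, 274–3313, 7717–8526 and 8357–9141 in CAC against NCAC. It gave 0–18 in NCAC against Con at 4 weeks, 0 at its other weeks, 665–3143 for CAC across weeks and 0 for NCAC. CAC across weeks moved from 1497 to 5101 with array weights, 3251 without both libraries apart, 949 without a filter, 564 with a replicate block, 562 length corrected, 527 rescaled, 479 with voom, 402 without mitochondrial genes and 269 with only the groups compared. CAC against Con moved at 2 weeks to 390 with array weights and 2 with the groups compared only. At 4 weeks it moved to 1160 with the groups only, 1645 length corrected, 1691 without mitochondrial genes, 1822 rescaled and 1834 with voom. It moved at 6 weeks to 3866 rescaled, 4092 length corrected and 4600 without mitochondrial genes, and at 8 weeks to 5517 rescaled and 5508 length corrected. CAC against NCAC moved at 2 weeks to 888 with array weights, 94 with the groups only, 57 rescaled, 52 without mitochondrial genes, 48 length corrected and 43 with voom. At 4 weeks it moved to 431 with the groups only, 768 without mitochondrial genes, 833 with voom, 915 length corrected, 954 rescaled and 1585 without a filter. It moved at 6 weeks to 5084 rescaled and 5133 length corrected, and at 8 weeks to 5499 and 5380. NCAC against Con moved from 0 at 2 weeks to 17 with array weights, 1 with the groups only and 1 without a filter, and at 8 weeks to 2 without a filter. In CAC against NCAC, rescaling turned Aldoa (-0.00472), Eif4g1 (-0.0313), Gys1 (-0.0126) and Myh4 (-0.146) at 6 weeks and Gys1 (-0.0441) at 8 weeks, and the length correction turned Myh4 at 6 weeks (-0.0794). The extracellular matrix list turned when rescaled at 8 weeks in CAC against Con (adjusted p = 0.98) and in CAC against NCAC (0.878; 0.957 length corrected). Among named genes, calls were lost in 71 cases with the groups only, 63 rescaled, 53 length corrected, 42 with voom and 34 without mitochondrial genes, and gained in 36 with array weights. Camera calls of lists were lost in 107 cases with an estimated correlation. Rescaling and the length correction both centre each library, so that they remove the common shift by construction; for the other moves the cause was not tested. The estimated depth of 39.62 to 48.34 M reads limits genes near 1 TPM most.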

Other observations

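The tests of the relations below were set out before their results were seen, and the remarks on Apoa1 and the genes beside it were chosen only after their values were seen.

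Apoa1, which encodes a lipoprotein of plasma, was lower in CAC than in NCAC at 4 weeks, at 0.718 ± 1.54 TPM in CAC and 9.30 ± 12.3 TPM in NCAC (SD, n = 5; log2 difference -1.84, adjusted p = 0.0189). Fabp1 (-1.44, adjusted p = 0.0254), Serpina3k (-1.43, adjusted p = 0.0346) and Serpina1c (-1.34, adjusted p = 0.0228) were lower as well, while the plasma protein gene Hp was higher by 2.82, and no list of such genes was tested. The adjusted p of Apoa1 was 0.104 without CAC replicate 2, 0.107 without NCAC replicate 3, 0.0544 without NCAC replicate 4 and 0.162 with voom, so a few libraries could carry the difference.

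The spread between CAC libraries of the same week may tell which responses move together. Over the deviations of the 22 CAC libraries from their group means after rescaling, a higher STAT3 and acute phase score went with a lower nuclear oxidative phosphorylation score (r = -0.795, two-sided permutation p = 2e-05, adjusted over 8 relations p = 0.00016). A higher glucocorticoid score also went with a lower oxidative phosphorylation score (r = -0.705, adjusted p = 0.00381), although r was above 0 within 1 of the 4 weeks. A higher glucocorticoid score went with a higher ubiquitin ligase score as well (r = 0.678, adjusted p = 0.00316). Without the 2 farthest libraries these were -0.739, -0.486 and 0.593, and without rescaling -0.804, -0.854 and 0.822. The STAT3 and ligase scores were not shown to be related (r = 0.289, adjusted p = 0.32), but without rescaling r was 0.571, so this depends on the scaling. In the 40 Con and NCAC libraries none of the 4 relations was called, at r of -0.0768, 0.189, 0.183 and 0.174 in the order given, and 0.0285, 0.214, 0.207 and 0.385 without rescaling, which was not tested.

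These relations suggest that ligase genes could follow glucocorticoid signalling (r = 0.678). Whether they follow it more closely than STAT3 signalling was not tested, and the gap between the r values depended on the scaling (0.678 and 0.289, and 0.822 and 0.571 without rescaling). Blocking the glucocorticoid receptor in muscle of mice with cachectic cells would test this, with Trim63 and Fbxo32 expected to stay low. Blocking STAT3 would test the other relation (r = -0.795), with oxidative phosphorylation genes expected to keep their level. A stage of disease shared by all scores is a possible explanation for each r and would be tested by weighing the muscle of each mouse.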
